A study of Homo sapiens with 6 samples.

How the data were processed

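Total RNA of MCF-7 cells grown in 5% calf serum was purified with Trizol and RNeasy columns, labelled with biotin by the one-cycle protocol and hybridised to Affymetrix U133A 2.0 arrays, per the labels' protocols. The 6 arrays formed 2 groups of 3, cells with an shRNA against NAMPT and control cells with an shRNA against luciferase. The values deposited were log2 signals, 1 per probe set and array, in a table for the whole series. The software GCOS is named in the submitters' processing notes, and its version, settings and scaling target, and the software that took logs and centred the values, are not given in the sources used here. That the deposited values were log2 signals, centred on each probe set's median, was read from the values. Every row had a median of 0 within 5e-07, and differences between arrays fell on log2 ratios of small whole numbers.

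Brightness was needed for the filter, for the choice of a probe set and for the variance trend, and centring had removed it. It was recovered by searching, for each probe set, for the smallest whole numbers of signal steps whose log2 ratios gave the 6 values, after 1 shift per array, with a relative tolerance of 1.5e-06 and at most 20000 steps. Steps were found for 20269 probe sets (91.0%), and the 2008 others were taken as brighter than the limit. With noise added to 3000 rows, 0.07% gave a match, and read as natural or common logarithms 0.27% and 5.93% of the rows did. On simulated rows within the limit, 98.2% of 2770 gave the exact steps. A tolerance of 1e-06 with up to 30000 steps was tried first. It left 519 probe sets with an SD over 0.8 without steps, and so among the bright ones, against 2 with the setting used, so the setting used was chosen after seeing the data, and the first is given as an alternative. The step in signal units and absolute levels stay unknown. The medians of the recovered levels of the 6 arrays lay within 0.02 on the log2 scale, so no further normalization was applied. Centred column medians ran from −0.03 to 0.02.

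Probe sets were named by the platform annotation, updated through gene identifiers with a RefSeq gene table of the assembly GRCh38.p14, of which no coordinates are printed. Of the 22215 probe sets other than controls, 19064 had 1 gene symbol, 1043 several and 2108 none, and 19052 of the first matched the gene table. Those with several symbols or none were left out of the gene comparisons. Each of 11963 genes was represented by its brightest probe set, and genes below the 40th percentile of brightness were left out, which left 7887. Probe sets without steps could not be ranked by brightness. Among those of the same gene the choice followed the ending (_s and _x last) and then the identifier.

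Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a trend on the recovered brightness) without a block, and p was adjusted by the Benjamini-Hochberg method with a threshold of 0.05. All tests were two-sided. The design had been written for values with their levels. Since levels had been removed, the recovered brightness took their place. The 28 gene lists were tested with camera (preset correlation 0.01, on the moderated statistics, NAMPT left out) where at least 5 genes were tested, and with an estimated correlation and with fry as alternatives. The genes named are NAMPT, the 12 with the largest positive and the 12 with the largest negative difference among the other genes past the threshold with non-overlapping groups, and up to 4 members of each list with the smallest p. A gene given only by probe sets with several genes is not named. CCNE2 and the other genes outside this rule were chosen after their values were seen. Lists, the tests of genes and lists, this rule and most alternatives were fixed before the data were examined. The checks on the DNA replication list and on CAV1 and CAV2 were framed on results already seen.

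The procedure was tested on simulated data for 7887 genes and the comparison of 3 control with 3 knockdown arrays, with 200 genes changed. It recovered 37.3% of 67 genes changed by 0.5 on the log2 scale, 73.1% of 67 changed by 1 and 97.0% of 66 changed by 2, with 9 false among 147 calls. In 20 simulations without changes at most 1 gene passed and no list did. The simulated variances were drawn around a curve on the recovered brightness, so the trend held by construction. The recovery of brightness, the filter and the choice of probe set were not part of the simulation, which does not test them. The simulated genes were drawn independently, so the list result does not cover lists whose genes correlate. In the data the estimated correlation within a list reached 0.61. Alternatives covered quantile normalization, median centring, scaling to the mean of the poly-A control probe sets, pseudocounts on the recovered signals, the filter, the trend, the choice of probe set, each array left out, the replicate number as a block, and other list tests. Arrays of 1 group differed with an SD between 0.35 and 0.38 on the log2 scale, and no 2 were copies. No scan date or batch was given in the sources used here. A single shRNA against NAMPT was used, and its sequence was not used here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with numpy 2.4.6 and pandas 2.3.3.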

Results

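RNA from MCF-7 cells, an established human breast cancer line of luminal type that expresses the estrogen receptor, was measured on 6 Affymetrix U133A 2.0 arrays, which carry short oligonucleotide probe sets for human transcripts. In 3 arrays the cells stably carried a retroviral short hairpin RNA (shRNA) against NAMPT, the enzyme that makes nicotinamide mononucleotide in the NAD salvage pathway. The other 3 arrays held control cells with an shRNA against luciferase, and the labels describe the replicates as independent and biological. The table gave 22277 probe sets, of which 62 were manufacturer's controls. The values were log2 signals centred on the median of each probe set over the 6 arrays, so that only differences between arrays could be read from them directly. With 3 arrays per group, the number of arrays limited the precision.

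The first comparison asked whether NAMPT mRNA was lower in the cells with the NAMPT shRNA. NAMPT fell by 1.79 on the log2 scale (SE 0.15, limma adjusted p = 5.2e-06), to 28.8% of the control signal, with a 95% confidence interval from 23.2% to 35.9%. Its centred signal was 0.80 ± 0.09 (SD, n = 3) in the control arrays and −0.99 ± 0.31 (SD, n = 3) in the knockdown arrays, and the groups did not overlap. These values are from the brighter of its probe sets. The other NAMPT probe set differed by −1.81 (SE 0.13), from 0.94 ± 0.14 (SD, n = 3) to −0.87 ± 0.08 (SD, n = 3). NAMPT ranked number 3 of the 7887 genes tested when ordered by p. Without the recovered brightness levels its difference was −1.80 and its adjusted p was 0.0631.

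**Figure D1:**
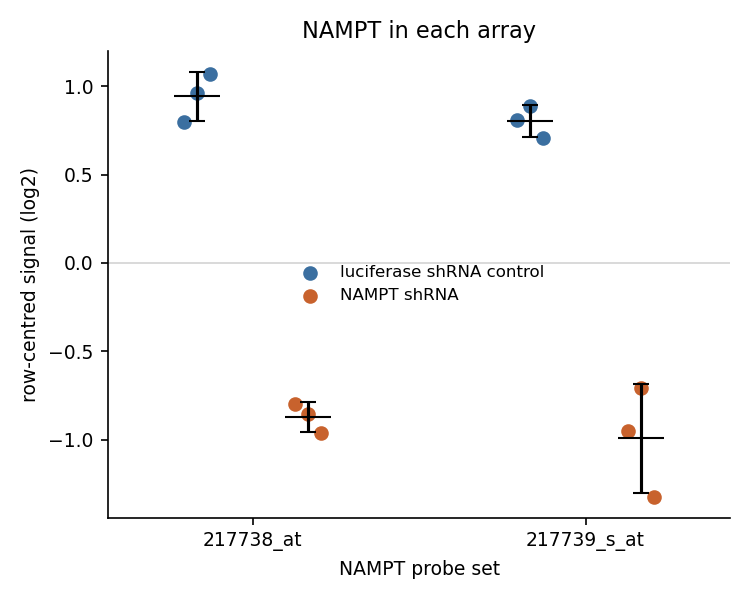
Row-centred log2 signal of NAMPT (vertical axis) for its probe sets (horizontal axis) in each control and knockdown array. Points are arrays, and the horizontal bars with whiskers are the mean and SD of 3 arrays. For the brighter probe set, on the right, the control arrays lay between 0.71 and 0.89 and the knockdown arrays between −1.32 and −0.71.

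The second comparison asked which genes differed between knockdown and control cells. Besides NAMPT, the genes that fell most were NELL2, a secreted glycoprotein, which was 3.60-fold lower (log2 difference −1.85, SE 0.10), and SOCS2, a suppressor of cytokine signalling, which was 2.79-fold lower (−1.48, SE 0.15). TFPI, the inhibitor of the tissue factor pathway of coagulation, rose most, by 2.37-fold (log2 difference 1.24, SE 0.21). In all, 33 genes were higher and 70 were lower in the knockdown arrays at a limma adjusted p under 0.05, among 7887 genes tested. The 103 genes all had non-overlapping groups, as did 1522 of all genes tested (19.3%, where chance gives 10%). The poly-A controls, bacterial transcripts added to the RNA before labelling, differed as well. Over 24 probe sets of Dap, Lys, Phe and Thr the median log2 difference between knockdown and control arrays was −0.39 (from −0.56 to −0.22), and in 22 the groups did not overlap. These probe sets read the same few added transcripts, so they are not independent observations. Their array means were 0.11, 0.35 and 0.07 in the control arrays and −0.04, −0.36 and −0.27 in the knockdown arrays. Over 18 probe sets of the Bio and Cre controls, added before hybridisation, the median was −0.07 and none had non-overlapping groups. Scaled to the poly-A controls, the median of all genes was 0.35, with 2103 genes higher and 16 lower, of the 103 genes 44 still passed and 93 kept their sign, so all directions given are relative to the scaling of the arrays as deposited. That scaling moves all genes of an array alike, so its counts carry the offset of the controls. As deposited, most of the changes were small. Of the 103 genes, 57 changed by less than 1.5-fold, and 1 higher and 9 lower genes changed by at least 2-fold.

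The next lower genes were of various kinds. TMPRSS3, a transmembrane serine protease, fell by 1.31 on the log2 scale (SE 0.24) and CAV1, the coat protein of caveolae, fell by 1.26 (SE 0.23). TFF3, a secreted trefoil peptide, fell by 1.02 (SE 0.09), and SCNN1A, a subunit of the epithelial sodium channel, fell by 0.91 (SE 0.20). NAT1, an arylamine N-acetyltransferase, fell by 1.16 (SE 0.08), the nucleotidase NT5C by 1.11 (SE 0.24), and CRYM, which binds thyroid hormone, by 1.05 (SE 0.22). MARCKS, a substrate of protein kinase C, fell by 0.93 (SE 0.10), the cyclin-dependent kinase CDK14 by 0.92 (SE 0.20), and the imprinted gene PEG10 by 0.90 (SE 0.11). The adjusted p of these genes lay between 3.67e-08 for NELL2 and 0.0336 for NT5C. A second SOCS2 probe set differed by −1.22 and a second PEG10 probe set by −0.82. With 1 array left out, CRYM and SCNN1A did not pass in 5 of 6 fits, NT5C and CDK14 in 4 and TMPRSS3 in 2, and NELL2, SOCS2, CAV1, TFF3, NAT1, MARCKS and PEG10 passed in all 6. Without a filter TMPRSS3, NT5C, CRYM, CDK14 and SCNN1A did not pass, nor did NT5C with quantile normalization (adjusted p = 0.0539). Without a trend TMPRSS3, NT5C, CRYM, CDK14 and SCNN1A did not pass, nor did CAV1 and PEG10 (limma adjusted p = 0.113 for both). With the narrower search for brightness, only NELL2 and NAT1 of the lower genes named so far besides NAMPT passed. Among dimmer probe sets not used for the test, 1 of MARCKS differed by 0.53 and the others of SCNN1A by 0.29 and 0.11, in the opposite direction, with SEs of 0.62, 0.46 and 0.54.

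The higher genes after TFPI were PLBD1, which has a phospholipase B domain, with a log2 difference of 0.82 (SE 0.16), and TMOD3, a capping protein of actin filaments, with 0.80 (SE 0.10). FBRS differed by 0.75 (SE 0.15), the cytochrome P450 enzyme CYP4B1 by 0.74 (SE 0.12), and GPER1, a G protein-coupled receptor for estrogen, by 0.74 (SE 0.17). The phospholipid flippase ATP8B1 differed by 0.71 (SE 0.15), ATXN10 by 0.66 (SE 0.10), and the secreted hormone STC1 by 0.64 (SE 0.12). EPS15, an adaptor of endocytosis, differed by 0.64 (SE 0.09), ASS1, which makes argininosuccinate from citrulline, by 0.63 (SE 0.09), and the sulfhydryl oxidase QSOX1 by 0.60 (SE 0.11). All TFPI, STC1, GPER1 and EPS15 probe sets differed in the same direction. With 1 array left out, GPER1 did not pass in 5 of 6 fits, PLBD1 and ATP8B1 in 4, FBRS and QSOX1 in 3 and STC1 in 2, and the 6 others passed in all. GPER1 also did not pass with quantile normalization (adjusted p = 0.0646), median centring (0.054), no filter (0.121) or no trend (0.236), nor did PLBD1 and ATP8B1 without a filter. Without a trend, TMOD3 was the only one of the 12 higher genes named to pass, and TFPI had a limma adjusted p of 0.147. With the narrower search for brightness none of the 12 passed, TMOD3 with 0.054. The other ATXN10 probe set, which was dimmer, differed by 0.15 (SE 0.32). ATXN10 did not pass with the mean of all probe sets (0.41, adjusted p = 0.202) or with probe sets without _s or _x endings first (0.15, adjusted p = 0.86), and with the latter MARCKS (−0.43, adjusted p = 0.536) and GPER1 (0.74, adjusted p = 0.054) did not pass either. With the mean of all probe sets, TFPI (1.04), GPER1 (0.76), CAV1 (−1.01), NT5C (−1.11), MARCKS (−0.38), CDK14 (−0.62) and SCNN1A (−0.17) did not pass either. The adjusted p of these 12 genes lay between 0.000433 for TMOD3 and 0.0469 for GPER1.

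**Figure D2:**
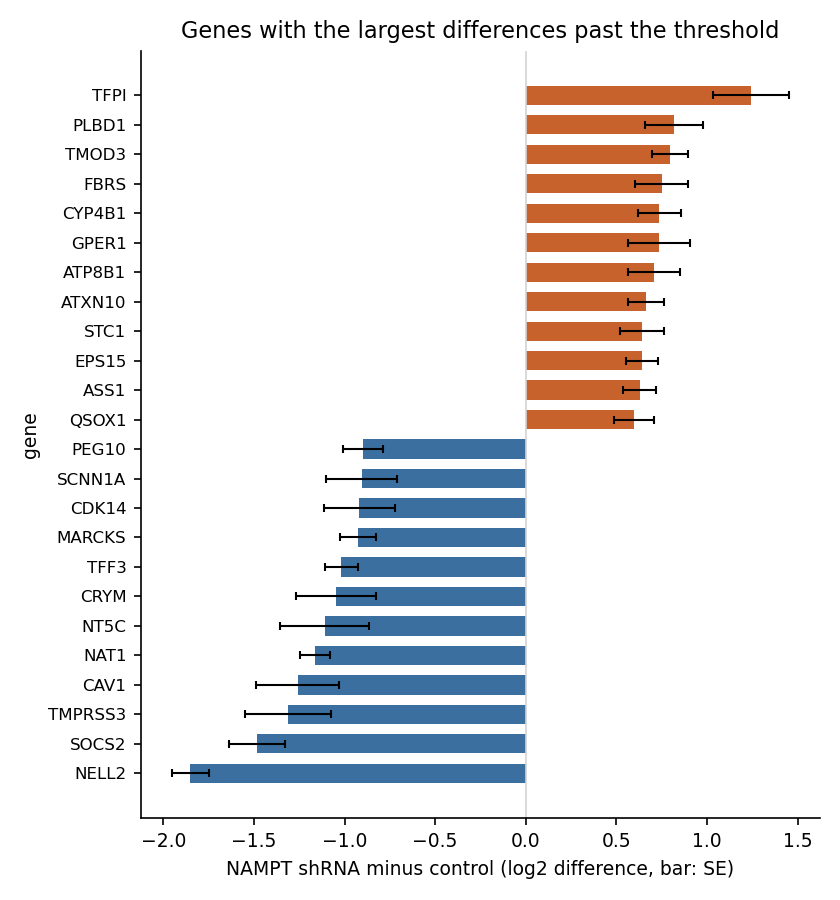
Log2 difference between knockdown and control arrays (horizontal axis) for the 12 genes with the largest positive and the 12 with the largest negative difference among genes past the threshold, NAMPT left out (vertical axis). Bars are the fitted difference of 3 knockdown and 3 control arrays, and whiskers its SE. The differences ran from −1.85 for NELL2 to 1.24 for TFPI.

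The number of genes past the threshold depended strongly on the processing. Without a brightness trend 1 gene was higher and 7 were lower, with the narrower search for brightness, which was tried first and replaced after its results were seen, 1 was higher and 4 were lower, and without recovered brightness none passed. That last fit also had no filter and took the mean of all probe sets of a gene, and 997 of its 11963 genes (8.3%) had an unadjusted p under 0.05, against 1169 of 7887 (14.8%). Quantile normalization changed the division from 33 higher and 70 lower (32.0% higher) to 51 higher and 55 lower (48.1% higher). Leaving out 1 array gave 9 higher and 26 lower genes without control replicate 2, 15 and 33 without control replicate 3, 21 and 27 without knockdown replicate 2, 12 and 38 without knockdown replicate 3, 21 and 72 without knockdown replicate 1, and 73 and 89 without control replicate 1.

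The third comparison asked whether lists of genes moved together. Of 28 lists, 27 had at least 5 genes tested, and 1 passed camera with a preset correlation. Genes of DNA replication and entry into S phase were lower, with a median log2 difference of −0.26 over 43 genes, 42 of which had a negative difference (camera adjusted p = 4.21e-12), while scaled to the poly-A controls its median was 0.15, against 0.35 for all genes. The call was lost with an estimated correlation between genes (adjusted p = 0.262) and with fry's test of direction (adjusted p = 0.160). Over all genes tested 5 of the 43 fell and 38 did not pass. Adjusted over the list alone, 19 fell. RRM2, a subunit of ribonucleotide reductase, fell by 0.59 (SE 0.09, limma adjusted p = 0.00188), and CCNE2, a cyclin of the G1/S transition, by 0.62 (SE 0.13, adjusted p = 0.0218). PRIM1, the catalytic subunit of primase, fell by 0.52 (SE 0.10), RFC4, a subunit of the clamp loader, by 0.41 (SE 0.08), and GINS1, a subunit of the replicative helicase complex, by 0.40 (SE 0.08). A second RRM2 probe set differed by −0.36. The list's mean centred signal was 0.02, 0.16 and 0.20 in the control arrays and −0.08, −0.11 and −0.16 in the knockdown arrays. The poly-A controls, with a median of −0.39, were lower in the same arrays. No list passed with an estimated correlation or with fry's test of direction, where 3 lists had an unadjusted p under 0.05 with camera and 4 with fry, while 12 lists passed fry's test of change in either direction.

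Genes of mitosis had a median difference of −0.002 over 39 genes. Of these, ZWINT, a kinetochore protein, fell by 0.41 (SE 0.08, limma adjusted p = 0.0203) and 38 did not pass, with 1 lower when adjusted over the list alone. CENPF, another kinetochore protein, differed by 0.66 (SE 0.21) in 1 probe set and by −0.88 (SE 0.62) and −0.44 (SE 0.25) in dimmer ones, and ECT2, an exchange factor of cytokinesis, by 0.29 (SE 0.09), without passing. Among 13 histone genes the median was −0.10. The linker histone gene H1-2 fell by 0.47 (SE 0.11, limma adjusted p = 0.0438), 12 did not pass, and 2 were lower when adjusted over the list alone. H4C8 had a difference of −0.43 (SE 0.11) and did not pass. A probe set annotated to several histone H4 genes, H4C8 among them, was left out of the gene comparisons. Tested by itself among all probe sets, it fell by 1.69 (SE 0.20, limma adjusted p = 0.00071).

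**Figure D3:**
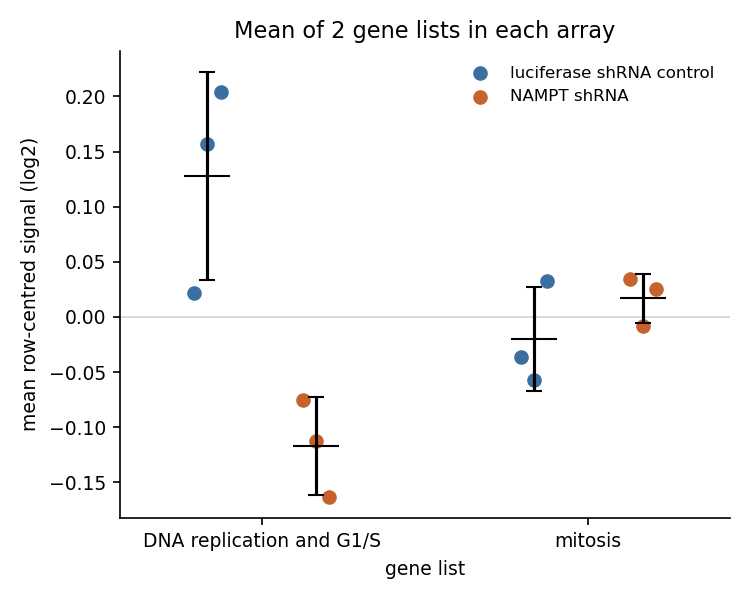
Mean row-centred log2 signal (vertical axis) of 43 DNA replication genes and 39 mitosis genes (horizontal axis) in each array. Points are arrays and the bars with whiskers the mean and SD of 3 arrays. The replication genes lay between 0.02 and 0.20 in the control arrays and between −0.16 and −0.08 in the knockdown arrays as deposited (the list median was 0.15 when scaled to the poly-A controls), and the mitosis genes of both groups lay between −0.06 and 0.03.

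Genes of NAD metabolism other than NAMPT showed few differences past the threshold. None of 9 other genes of NAD synthesis and salvage passed over all genes tested, and 1 was higher when adjusted over the list alone. QPRT, which makes nicotinic acid mononucleotide from quinolinate, differed by 0.90 (SE 0.24, limma adjusted p = 0.0797), the kynureninase gene KYNU by 0.27 (SE 0.10), and the nucleoside phosphorylase gene PNP by −0.19 (SE 0.09). The median of this list was −0.13 and its mean 0.10, and camera's direction was upward (adjusted p = 0.415). Among 17 enzymes that consume NAD, TNKS2, a poly-ADP-ribosylating tankyrase, rose by 1.38-fold (log2 difference 0.46, SE 0.10, limma adjusted p = 0.0339) and 16 did not pass. The count was also 1 when adjusted over the list alone. PARP2 differed by −0.31 (SE 0.10), PARP11 by −0.86 (SE 0.36) and SIRT1 by 0.23 (SE 0.11). The median of these 17 genes was −0.11.

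Among 28 genes induced by estrogen, 2 fell and 26 did not pass, and 1 was higher and 6 lower when adjusted over the list alone. The chemokine gene CXCL12 fell by 0.56 (SE 0.10, limma adjusted p = 0.00955) and the trefoil peptide gene TFF1 by 0.33 (SE 0.08, adjusted p = 0.0476). Scaled to the poly-A controls, which moves all genes upward alike, TFF1 differed by 0.07, against a median of 0.35 for all genes. The cyclin gene CCND1 differed by 0.25 (SE 0.08) and ELOVL2 by −0.29 (SE 0.10), without passing. The list's median was −0.12 (camera adjusted p = 0.211). Among 22 genes of luminal identity NAT1 and TFF3 fell and 20 did not pass, with a median of −0.07. Adjusted over the list alone, 2 were higher and 3 lower. The claudin gene CLDN3 differed by 0.71 (SE 0.19, limma adjusted p = 0.0851) in 1 probe set and by −0.14 (SE 0.15) in another of similar brightness, and the transcription factor gene ELF3 by 0.49 (SE 0.13, adjusted p = 0.0836).

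Markers of other cell types were examined as well. Among 15 mesenchymal and stromal genes, CAV1 and its partner CAV2 fell, CAV2 by 0.81 (SE 0.14, limma adjusted p = 0.0103), and 13 did not pass. The same number, 2, was lower when adjusted over the list alone. TWIST1 differed by −0.55 (SE 0.21) and the thrombospondin gene THBS1 by −0.31 (SE 0.12). This list had the lowest median of all, −0.31 (camera adjusted p = 0.211). Of 6 basal epithelial genes none passed over all genes and 1 was higher when adjusted over the list alone. The integrin gene ITGB4 differed by 0.70 (SE 0.23) in its brightest probe set and by −0.21, −0.99 and −1.87 in the others. EGFR differed by 0.28 (SE 0.23), with other probe sets in both directions, and the median was −0.02. Only 4 leukocyte and endothelial genes were bright enough, so that list was not tested. LCP1 differed by 0.07, FCER1G by −0.17, LAPTM5 by −0.14 and CD79B by −0.07, and none passed.

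Stress and signalling lists held few genes past the threshold. Of 25 targets of p53, KITLG, the ligand of the KIT receptor, rose by 1.40-fold (log2 difference 0.48, SE 0.10, limma adjusted p = 0.0210) and 24 did not pass. Adjusted over the list alone, 2 were higher and 2 lower, and the median was −0.05. BHLHE40, a transcriptional repressor in the hypoxia and clock lists, fell by 0.61 (SE 0.11, adjusted p = 0.00858). It was 1 of 25 hypoxia genes (median −0.03, 2 lower over the list alone) and 1 of 17 clock genes (median −0.10, 1 lower over the list alone), and the rest did not pass. None passed, over all genes or over the list alone, among 36 genes of the ATF4 response (median −0.06), 24 of the endoplasmic reticulum (−0.02), 19 heat shock genes (−0.03), 22 NRF2 targets (0.03), 22 FOXO targets (−0.03), 15 NF-kB targets (0.02), 18 interferon-stimulated genes (−0.005), 28 immediate early genes (−0.11) and 21 genes of the BCL2 and caspase families (median 0.001). The chemokine gene CCL2 had a difference of 0.84 (SE 0.25, limma adjusted p = 0.111), the serine synthesis gene PSAT1 of 0.55 (SE 0.23), and LGALS3BP of 0.57 (SE 0.17).

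In the metabolic lists, INSIG1, which retains the activator of sterol synthesis in the endoplasmic reticulum, rose by 1.26-fold (log2 difference 0.33, SE 0.08, limma adjusted p = 0.0460). It was 1 of 19 cholesterol genes, of which 18 did not pass, with a median of −0.06. Adjusted over the list alone, 1 was higher and 1 lower, and ACAT2 differed by −0.29 (SE 0.08). None of 19 glycolysis genes (median 0.02), 23 genes of the TCA cycle (−0.05), 58 of oxidative phosphorylation (−0.08), 14 of fatty acid synthesis (0.01) or 50 cytoplasmic ribosomal protein genes (−0.04) passed, over all genes or over the list alone. In oxidative phosphorylation 50 of the 58 differences were negative (camera adjusted p = 0.165, and 0.948 with an estimated correlation). Negative differences also made up 43 of 50 for ribosomal proteins, 17 of 23 for the TCA cycle and 14 of 19 for cholesterol. They were 9 of 19 for glycolysis and 7 of 14 for fatty acid synthesis. SDHC, a subunit of succinate dehydrogenase, had a difference of −0.27 (SE 0.09) and PGK1, a glycolytic kinase, of −0.24 (SE 0.08). Other SDHC probe sets differed by −0.16, −0.09 and −0.19, and other PGK1 probe sets by −0.08, −0.16 and 0.35. The median of all genes tested was −0.05. Of 128 named genes 58 had several probe sets, and in 21 of these, including KYNU, THBS1 and PGK1, at least 1 probe set differed in the opposite direction. In 9 lists the median and the mean differed in sign, and in 9 the median and camera's direction did.

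**Figure D4:**
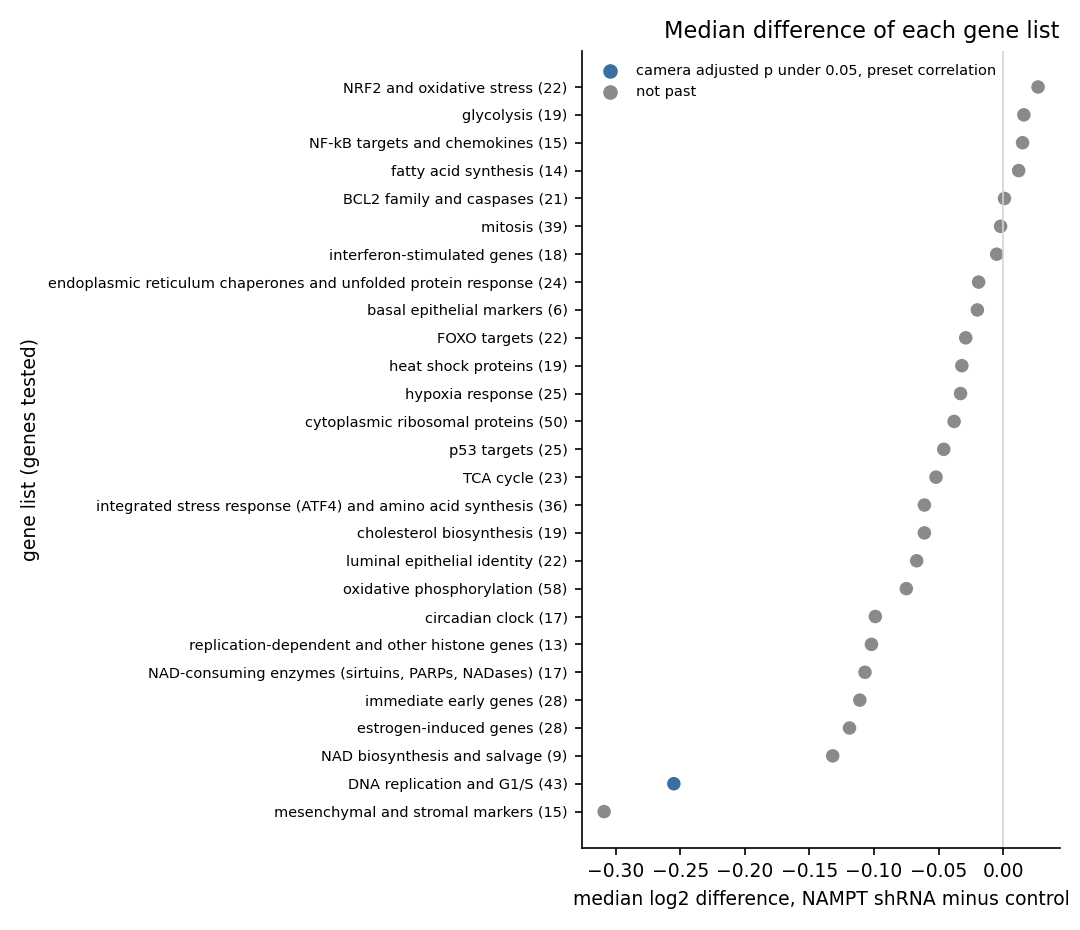
Median log2 difference between knockdown and control arrays (horizontal axis) of the 27 lists tested (vertical axis, with the number of genes tested). Each point is a list, blue where camera with the preset correlation gave an adjusted p under 0.05. The replication list, at −0.26 (0.15 when scaled to the poly-A controls, with 0.35 for all genes), was the 1 list past that threshold, a call lost with an estimated correlation (adjusted p = 0.262) and with fry's test of direction (adjusted p = 0.160), and the mesenchymal list had the lowest median, −0.31.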

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

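Signal differences also appeared in probe sets that the gene comparisons leave out. When each of 13329 probe sets bright enough was tested by itself with limma, 19 of the 1472 with no single gene name passed an adjusted p under 0.05, of which 6 were higher and 13 lower in the knockdown arrays. Among all 13329, 51 were higher and 99 lower, so a similar share passed. Of the 19, 9 are annotated to several genes and 10 to none. Some of the 9 share their genes, as those of TARP and TRGC2 and those of TMSB15A and TMSB15B do. No explanation was tested for them.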

How the results depend on the processing

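The main search for brightness was itself chosen after seeing the data, in place of the narrower one tried first, which gave 5 genes against 103. The pseudocounts on recovered signals, the fit without recovered brightness and the scaling to the poly-A controls were chosen after seeing the data. NAMPT differed by −1.94 to −1.39 over all 20 alternatives and passed in all but the fit without recovered brightness (−1.80, adjusted p = 0.0631, range 6.9e-10 to 0.0631), and the DNA replication list had a median from −0.29 to 0.15 over 23 alternatives. The positive value came from scaling to the poly-A controls, which moved the median of all genes to 0.35 and gave 2103 higher and 16 lower genes (99.2% higher against 32.0%), 3 lists and TFF1 at 0.068, the opposite of its main direction. The list kept its camera call in every refit of the genes. With camera's estimated correlation (−0.26, adjusted p = 0.262), where 0 lists passed, and with fry's test of direction (−0.26, adjusted p = 0.160), where 0 lists passed, it did not, over a range of 1.21e-15 to 0.262. Fry's test of change in either direction gave 12 lists. Against 33 higher and 70 lower genes, 51 were higher with quantile normalization. There were 17 and 36 without a filter, and 51 and 108 with a filter at the 60th percentile. The counts were 1 and 7 without a trend, 18 and 42 with the mean of all probe sets, and 1 and 4 with the narrower search. They were 0 and 0 with limma without recovered brightness (997 of 11963 genes at an unadjusted p under 0.05). With every probe set by itself the unit was the probe set and not the gene. There 51 were higher and 99 lower of 13329 probe sets. Leaving out 1 array gave 9 to 73 higher genes, 26 to 89 lower genes and 1 to 2 lists, the 2 without control replicate 1. There were 3 lists without a filter and 4 without recovered brightness. The cause was not tested for these. Of the 103 genes, 8 remained without the trend, 52 without the filter, 4 with the narrower search, 44 with scaling to the poly-A controls, and between 33 (without control replicate 2) and 92 (without control replicate 1) with 1 array left out. The labels number the replicates of both groups alike. Arrays with the same number had deviations that correlated by 0.01, −0.01 and 0.05 across genes, and not every array correlated best with its own number, so the numbers were not taken to pair the arrays. The fit with the replicate number as a block gave 33 higher and 68 lower genes, of which 87 were among the 103. Of 1747 values of 127 named genes under the other alternatives, 1550 kept their side of the threshold, 154 no longer passed, 42 newly passed and 1, TFF1, reversed. Of those that kept their side, 66 changed sign without passing. With 1 array left out, 83 of 762 no longer passed, 6 newly passed and 6 changed sign without passing. For the 24 genes with the largest changes, 89 of 329 values no longer passed, and 41 of 144 with 1 array left out. Among the 26 other lists 7 of 362 values newly passed, and 1 of 156 with 1 array left out. The sign of the median changed in 49 and 32 values that stayed on their side. Background was not measured. Probe sets with up to 1000 steps had a median SD of 0.89 over the 6 arrays, against 0.10 for those brighter than the search limit.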

Other observations

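The tests of cycling cells, of scaling to the poly-A controls and of neighbouring genes among those past the threshold were chosen only after the result was seen. So were the number of genes under other splits and the genes named in the next paragraph. The other checks on the DNA replication list and on CAV1 and CAV2 were framed once these genes had been seen to be lower.

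Further genes were among the 70 lower ones. PRKACB, a catalytic subunit of protein kinase A, fell by 0.72 (SE 0.08, limma adjusted p = 0.000155), its inhibitor PKIA by 0.73 (SE 0.11) and the adenylate cyclase gene ADCY1 by 0.51 (SE 0.10). ITPR1, a calcium channel of the endoplasmic reticulum, fell by 0.88 (SE 0.15), RCAN1, a regulator of calcineurin, by 0.43 (SE 0.10), and CAMK2N1, an inhibitor of a calmodulin-dependent kinase, by 0.65 (SE 0.11). Among the higher genes were the metallothioneins MT1X, with a log2 difference of 0.51 (SE 0.10), and MT2A, with 0.39 (SE 0.08). They were read from probe sets of a kind that can share sequence with related genes. No list of these genes was tested.

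The DNA replication list was lower in the knockdown arrays as deposited, with 42 of 43 differences negative, while scaled to the poly-A controls its median was 0.15, against 0.35 for all genes. Its median minus that of all genes was −0.21 as deposited, with median centring and scaled to the poly-A controls. With quantile normalization it was −0.19. A shift of all genes alike cannot change this difference, and so does not account for it. A general lowering of genes of that brightness was too small to give the list's −0.26. Random lists matched on level, 10000 in all, had medians of −0.06 on average and −0.16 at the lowest (share 1e-04, the smallest they can give). They do not carry the correlation between the list's genes, estimated at 0.25, and the list was singled out by passing in these data. The share therefore does not tell how unusual the list is. In 1 split that mixed the groups, the list's median was 0.19 in size. An effect of 1 array alone is argued against, as the least negative median with an array left out was −0.21. Fewer cycling cells as the whole cause is argued against by the mitosis list, whose median was higher by 0.25. The mean of the mitosis list minus that of the replication list was −0.058, −0.213 and −0.172 in the control arrays. In the knockdown arrays it was 0.109, 0.105 and 0.188. The 95% bootstrap interval over genes, from 0.18 to 0.33, treats genes as independent and does not measure the spread between arrays. An effect of less NAMPT was not tested apart from the shRNA and stays open. So do an effect of the shRNA on other genes, a difference in growth between the cultures and correlation between the genes. A difference in RNA input or labelling stays open too, beyond a shift of all genes alike (the poly-A controls differed by −0.39, along with the groups).

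CAV1 and CAV2 were lower together. Mesenchymal cells in the control cultures are a candidate source, which stays open. VIM, FN1, COL1A1, COL1A2 and SPARC had a median of −0.38, and COL1A2 and SPARC were among the dimmest 40% of probe sets. The bootstrap interval over these genes, from −0.70 to 0.17, ends at the values of FN1 and COL1A1. It does not measure the spread between arrays, and so few genes could hardly decide the question. CAV2 and CAV1 are neighbours among the genes tested and TES is next to them, so a change of the whole neighbourhood is another candidate. Neighbouring genes past the threshold in the same direction made 5 pairs, where random placement gave 0.73 on average and 3 at the upper end of its 95% range. Without TES, CAV2 and CAV1 there were 3 pairs (share of random placements 0.036), which is not above that range, and so the test leaves this open.

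The pairs were TES with CAV2, CAV2 with CAV1, ITPR1 with BHLHE40, DKK1 with ZWINT and TFF1 with TMPRSS3, all lower. If segments of the genome differed between the cultures, neighbours could move together in general. The differences of neighbouring tested genes correlated by 0.029 across genes, which are not independent replicates, against −0.016 to 0.020 in the 9 other splits of the arrays. The excess over the highest of these was within the standard error of 0.011, so segments cannot be told apart from changes of single genes.

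Other splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. The real split gave 103 genes and the highest other split 1, so that 1 of 10 splits gave as many genes. For the lists the real split gave 1 and the highest other 3, and 7 of 10 splits gave as many lists.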
